A study of Mus musculus with 8 samples.

How the data were processed

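The data are RNA-seq counts from 8 samples of mouse lung myofibroblasts taken at postnatal day 7 on a C57BL/6 background, 4 labelled wild type and 4 labelled Fra-2 transgenic. Per the labels' protocols, total RNA was extracted with a column kit, mRNA was isolated from 50 ng of total RNA with oligo-dT beads, cDNA was amplified from it (NuGEN Ovation RNA-Seq System V2) and libraries were made with a transposase-based kit (Nextera XT). Amplification from little RNA adds spread between libraries, and the protocols name no step that marks the strand, so reads of overlapping or antisense genes cannot be told apart. Reads shared with near-identical copies of a gene make its count uncertain.

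The authors deposited 1 table of raw counts per gene, with 43432 mouse Ensembl gene identifiers and 1 column per sample. The submitters' processing notes name the genome build GRCh38, a human build, while the identifiers in the table are those of mouse genes. The aligner, the counting tool and the annotation are not given in the sources used here. Identifiers were matched to symbols, gene types and coordinates in the GENCODE M21 annotation of mouse build GRCm38 and in tables of gene names. 42462 had a symbol, and the others held 0.0892% of counts. Coordinates printed here are those of GRCm38 and were not taken from the deposited table. Each column name is the title of 1 sample, and groups were taken from the labels alone. Pairs of libraries within a group differed by far more than sampling noise, with a chi-square per gene of 39.8 to 176, and all 8 were kept as separate samples.

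Counts were analysed as deposited in R 4.3.3. Genes were kept by the filterByExpr function of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 15422 genes. Library sizes were scaled by TMM, dispersions were estimated robustly (common biological coefficient of variation 0.257), and groups were compared with edgeR's quasi-likelihood F-test, two-sided, with no covariate and with Benjamini-Hochberg adjustment at 0.05. Standard errors are the absolute log2 fold change divided by the square root of F, and intervals are 95%. The median log2 fold change of all tested genes was -0.0123. CPM values use TMM-scaled library sizes and the 4 against 4 comparison of Fosl2 was also run as a two-sided exact permutation test. Intervals cover the spread between these libraries. Total counts of 29926239 to 41335957 per library set the counting error.

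In advance, 46 gene lists were fixed, 27 of pathways and structures and 19 of other cell types and RNA quality, together with the alternatives and the rule for named genes. By that rule the text names Fosl2. It names in each direction the 12 largest changes past the threshold with a mean of at least 5 CPM and no overlap between groups, leaving out predicted genes and pseudogenes by the form of their symbols. One of the falls and a family test that needs it are not reported here. It names up to 3 called members of each biology list with the smallest adjusted p, or its most abundant member if none passed. For each other list it names its most abundant member and its most clearly called member. Members named outside the rule, among them those that passed or led only within their list, were chosen after their values were seen. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with its preset correlation of 0.01, two-sided and adjusted over the 46 lists. Camera with an estimated correlation and fry were alternatives. Counts of members are given over all genes tested and adjusted over the list alone.

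The other alternatives chosen before the data were examined were RLE, upper-quartile and total-count scaling, no filter and a stricter filter, DESeq2 1.42.0, limma-voom with and without sample weights, a fit without robust dispersion, replicate number as a block, leaving out the 20 most abundant genes, leaving out each library in turn, other prior counts, an adjusted p of 0.10 and a 2-fold minimum. Sex read from Xist and 4 Y-linked genes, the noncoding share of counts, each sex alone, mitochondrial ribosomal RNA left out, and the fit without control 1 and control 2 were added after the data were seen. The procedure was tested on counts simulated for the same 15422 genes and 8 libraries. The 200 changed genes, 50 at each size, were drawn from genes with a mean of at least 1 CPM. As a planted list, 20 elastic fibre genes were raised 1.5-fold. The procedure recovered 34% at 1.5-fold, 62% at 2-fold, 96% at 4-fold and 100% at 8-fold. Of 15202 unchanged genes, 18 were among its 175 calls (10.3%). Camera found the planted list (adjusted p = 1.73e-21) and called 0 of the other 45. The simulated genes varied independently of each other, while the real elastic fibre genes had an estimated correlation of 0.28. The simulation therefore cannot show how often camera calls lists of correlated genes by chance. By the recovery rates above, changes under 2-fold are often missed at this number of libraries. The rates do not cover tested genes with lower means than those drawn.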

Results

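Myofibroblasts from the lungs of mice at postnatal day 7 were profiled by RNA sequencing in 8 libraries. 4 libraries were labelled wild type (control 1 to control 4) and 4 were labelled Fra-2 transgenic (Fra-2 1 to Fra-2 4). Lung myofibroblasts are contractile, matrix-producing mesenchymal cells that lay down elastin while the alveolar walls form, and Fra-2, the product of Fosl2, is a member of the AP-1 family of transcription factors. The comparison asks which genes differ between the libraries labelled Fra-2 transgenic and the control libraries. Total counts were 41335957, 35761984, 31986025 and 33720401 in control 1 to control 4. They were 34780832, 29926239, 32656441 and 38954848 in Fra-2 1 to Fra-2 4. Judged by Xist and 4 Y-linked genes, each group held 2 female and 2 male libraries. The labels do not say whether the libraries came from separate animals, so p-values measure only the spread between these samples. Each group held both sexes, so this spread is not purely technical, but that between libraries of the same sex may be. Means are given ± SD over n = 4 libraries per group in CPM, the count scaled to library size, and log2 fold changes are given with their standard error (SE).

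Fosl2, the gene that the labels name as the transgene, was not higher in the libraries labelled Fra-2 transgenic. It measured 120 ± 15.0 CPM in the control libraries and 132 ± 25.7 CPM in the libraries labelled Fra-2 transgenic. The log2 fold change was 0.14 (SE 0.136, edgeR adjusted p = 0.888). The 4 libraries labelled Fra-2 transgenic measured 166, 134, 126 and 104 CPM against 105, 117, 141 and 119 CPM in the controls. A two-sided exact permutation test of these values gave p = 0.486, where 0.0286 is the smallest p that 4 against 4 allows. Each library held 3914 to 5746 reads on Fosl2 (ENSMUSG00000029135, chromosome 5, 32135801 to 32157842 in GRCm38). The 95% interval of the fold change ran from 0.898 to 1.34. A doubling of Fosl2 reads therefore lay outside the interval. For this reason the group is called by its label throughout, and every direction given here is that of the libraries labelled Fra-2 transgenic against the control libraries.

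**Figure D1:**
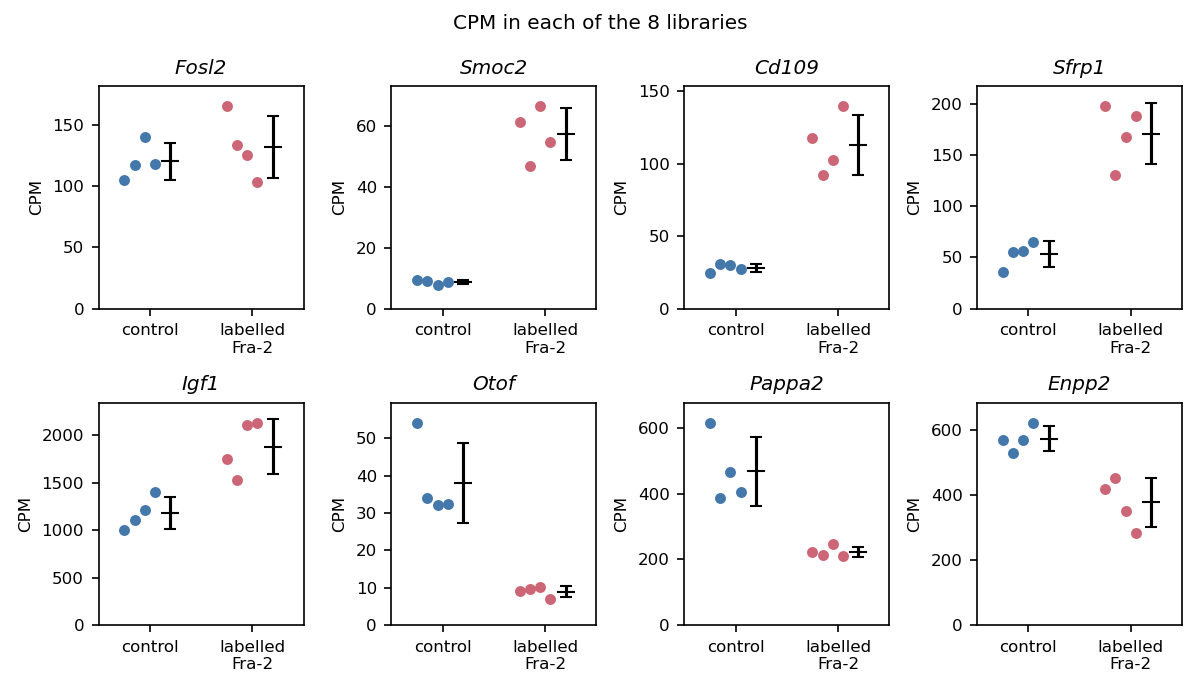
CPM (vertical axes, from 0) of 8 genes in each of the 4 control libraries and the 4 libraries labelled Fra-2 transgenic, as points, with the group mean and SD beside them as a dash with bars. The Fosl2 points of the groups overlap, while those of Smoc2, Cd109, Sfrp1, Igf1, Otof, Pappa2 and Enpp2 do not.

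In the libraries labelled Fra-2 transgenic, Smoc2, a secreted calcium-binding matrix protein, rose from 8.71 ± 0.691 to 57.3 ± 8.56 CPM, a log2 fold change of 2.72 (SE 0.142, edgeR adjusted p = 2.66e-07). Xaf1, an interferon-inducible gene that antagonises an inhibitor of apoptosis, rose from 3.01 ± 0.357 to 20.1 ± 3.14 CPM (log2 fold change 2.74, SE 0.174, edgeR adjusted p = 2.02e-06). Cd109, a membrane-anchored co-receptor that restrains TGF-beta signalling, rose from 28.3 ± 2.73 to 113 ± 20.7 CPM. Sfrp1, a secreted Wnt antagonist, rose from 53.2 ± 12.4 to 171 ± 29.8 CPM. In the other direction, Otof, which encodes the calcium sensor otoferlin, fell from 38.2 ± 10.7 to 8.97 ± 1.45 CPM (log2 fold change -2.09, SE 0.193, edgeR adjusted p = 0.000102). Smoc2 lies on chromosome 17 (ENSMUSG00000023886, 14279506 to 14404790 in GRCm38). Xaf1 lies on chromosome 11 (ENSMUSG00000040483, 72301629 to 72313733), in a stretch of 24.1 Mb that holds 15 of the called genes. Otof lies on chromosome 5 (ENSMUSG00000062372, 30367062 to 30461932).

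Over the 15422 genes tested, 111 were higher and 46 were lower in the libraries labelled Fra-2 transgenic (edgeR, adjusted p under 0.05). Of these 157 genes, 71 differed by at least 2-fold. In 156 of the 157 the 4 libraries of one group all lay above the 4 of the other, a separation seen in 5.76% of tested genes and given to 2.86% by chance. Protein-coding genes made up 155 of the called genes. Of the 157 calls, 60 (42 higher and 18 lower) stayed past the threshold without each library in turn. The count of higher genes moved to 50 without control 2, 67 without control 3, 54 without Fra-2 1, 50 without Fra-2 3 and 72 without Fra-2 4. That of lower genes moved to 26 without control 2, 23 without control 3 and 22 without Fra-2 1. DESeq2 called 269 higher and 104 lower. In the female libraries taken alone 142 higher and 37 lower genes passed, while 3 and 0 passed in the males. In the males 409 of 15837 tested genes had an unadjusted edgeR p under 0.05, a smaller share than the 0.05 that chance gives. With 2 against 2 libraries, this fit cannot show that the groups do not differ in males. All 157 calls had the same sign in the males, which largely follows from their groups not overlapping. The difference of the group effect between the sexes passed for 0 genes in edgeR. Of the 15422 genes, 294 had an unadjusted p under 0.05 for it, also a smaller share than chance gives.

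The 12 largest rises in the libraries labelled Fra-2 transgenic also included the 8 genes given here. Cdh13, the lipid-anchored T-cadherin, rose from 11.5 ± 2.19 to 35.3 ± 3.88 CPM (edgeR adjusted p = 0.00014). Mmp19, a matrix metalloproteinase, rose from 10.9 ± 3.14 to 32.8 ± 4.02 CPM (edgeR adjusted p = 0.000615). Lrrc8e, a subunit of the volume-regulated anion channel, rose by 2.07 on the log2 scale. Ociad2 rose by 2.39 and Sprn, a prion-related protein gene, by 1.74. The actin regulator Coro6 rose from 2.03 ± 0.343 to 8.16 ± 1.94 CPM. Tmem100, a membrane protein gene downstream of BMP signalling, rose from 4.57 ± 0.399 to 27.6 ± 14.9 CPM (edgeR adjusted p = 0.0138). Aldh1a2, which encodes a retinoic acid-synthesising enzyme, rose from 15.0 ± 2.82 to 48.2 ± 19.7 CPM (edgeR adjusted p = 0.0143). Both calls were lost in some of the fits without 1 library. The adjusted p of Tmem100 was 0.0848, 0.0523, 0.0512 and 0.0583 without control 1, 2, 3 and 4 in turn. That of Aldh1a2 was 0.0544 without control 1 and 0.0503 without control 3. Without Fra-2 2, the lowest library of its group for both genes, the adjusted p was 6.05e-06 for Tmem100 and 0.00029 for Aldh1a2.

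The 12 largest falls in the libraries labelled Fra-2 transgenic also included the genes given here. Atp1b1, the beta subunit of the sodium pump, fell from 46.1 ± 5.58 to 19.2 ± 2.55 CPM (edgeR adjusted p = 0.000346). Cds1, an enzyme of phosphatidylinositol synthesis, fell by 1.54 on the log2 scale and the fatty acid elongase Elovl7 fell by 1.62. The protocadherin Pcdh15 fell by 1.46 and the glycosyltransferase Galnt15 fell by 1.37. Slc24a4, a sodium, potassium and calcium exchanger, had a log2 fold change of -1.27, and Corin, the protease that activates atrial natriuretic peptide, one of -1.30. The values were -1.44 for Npy4r, a neuropeptide Y family receptor, -1.34 for Fam167a and -1.20 for Pirt, a regulator of TRP channels. These last 5 genes lost their calls when some single libraries were left out. Adjusted p reached 0.067 for Slc24a4 (without control 2), 0.113 for Corin (without Fra-2 1), 0.0997 for Npy4r (without control 3), 0.0571 for Fam167a (without Fra-2 2) and 0.128 for Pirt (without Fra-2 3). Slc24a4 also lost its call without Fra-2 1, and Corin without control 1, 2, 3 or Fra-2 3. Npy4r lost it without control 1, Fra-2 1 or Fra-2 3, Fam167a without control 2 or 3, and Pirt without every other library but control 2.

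**Figure D2:**
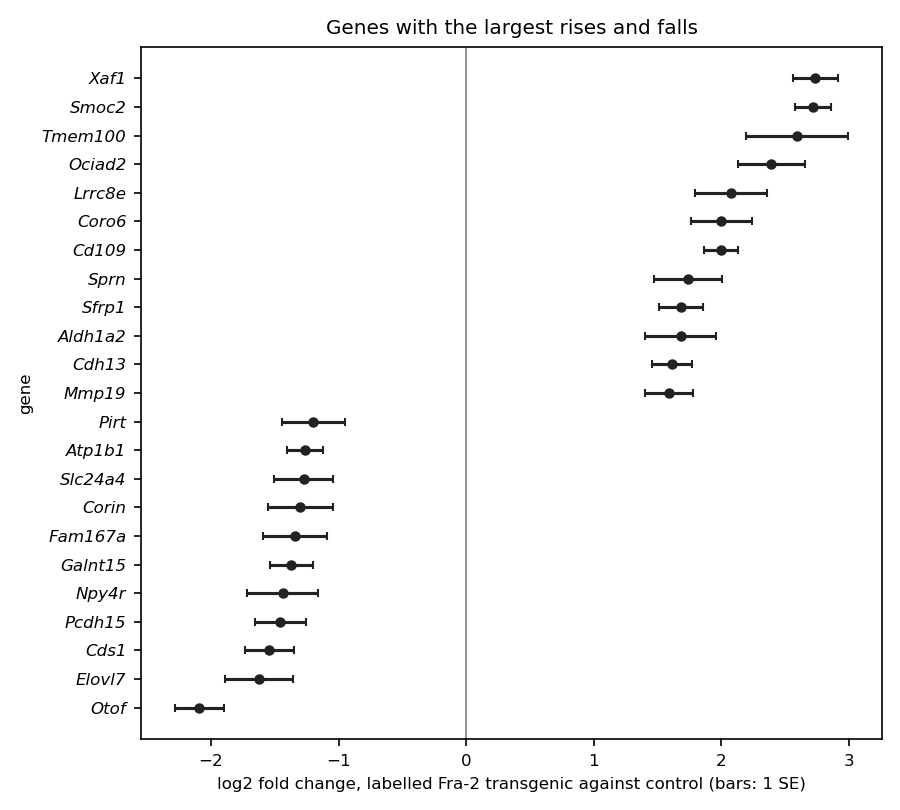
Log2 fold change of the libraries labelled Fra-2 transgenic against control (horizontal axis) for the 12 largest rises and 11 of the 12 largest falls chosen by the rule for named genes (vertical axis), as points with bars of 1 SE. Xaf1, Smoc2 and Tmem100 had the highest values (2.74, 2.72 and 2.59), and Otof had the lowest (-2.09).

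Genes of the insulin-like growth factor (IGF) axis moved in both directions in the libraries labelled Fra-2 transgenic. Igf1, the growth factor itself, rose from 1178 ± 167 to 1878 ± 288 CPM (edgeR adjusted p = 0.0222). Igfbp5, a binding protein of IGFs, rose from 1587 ± 65.1 to 2826 ± 235 CPM (edgeR adjusted p = 0.000424). Igfbp3, another binding protein, named after its values were seen, rose by 0.72 on the log2 scale. Pappa2, a protease that cleaves IGF-binding proteins, fell from 468 ± 104 to 223 ± 16.2 CPM (edgeR adjusted p = 0.00109). Of the 15 members of the IGF axis genes, 3 rose, 1 fell and 11 did not pass. Adjusted over the list alone, 5 rose and 1 fell. The list had a camera adjusted p of 0.0437 (adjusted p = 0.69 with an estimated correlation), which became 0.538 without control 1, 0.0602 without control 2, 0.101 without Fra-2 3 and 0.0841 without Fra-2 4. Igf1 lost its call without any one library other than control 4 and Fra-2 2 (adjusted p up to 0.098), and Igfbp3 without control 2, Fra-2 1, Fra-2 3 or Fra-2 4 (up to 0.117).

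Among the Wnt pathway genes, the antagonist Sfrp2 rose beside Sfrp1 in the libraries labelled Fra-2 transgenic, from 8.88 ± 1.39 to 17.6 ± 4.05 CPM. Lgr5, a receptor for R-spondins that amplifies Wnt signals, rose from 6.31 ± 1.38 to 12.3 ± 1.44 CPM. These 3 of 29 tested members rose, 0 fell and 26 did not pass. Adjusted over the list alone, 4 rose and 0 fell. The list as a whole passed (camera adjusted p = 0.00185, and adjusted p = 0.476 with an estimated correlation). Sfrp2 lost its call without control 2, Fra-2 1 or Fra-2 3 (adjusted p up to 0.0695) and Lgr5 without control 1, control 3, Fra-2 1 or Fra-2 3 (up to 0.107).

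In the libraries labelled Fra-2 transgenic, the matrix and adhesion lists given here passed upwards in camera with its preset correlation. Few of their members passed alone. None of these lists passed with an estimated correlation or in the directional test of fry. Of the 35 splits of the 8 libraries into 4 and 4, the real one included, 8 gave at least the real count of biology lists. Of 30 fibrillar collagen and interstitial matrix genes, 1 rose, 0 fell and 29 did not pass, and adjusted over the list alone 5 rose and 1 fell. The riser, the small proteoglycan gene Dcn, went from 140 ± 17.7 to 212 ± 30.2 CPM (edgeR adjusted p = 0.0323). The collagen genes Col1a1 (6056 and 5852 CPM in control and labelled transgenic libraries) and Col3a1 (6576 and 7107 CPM) did not pass. The list's median log2 fold change was 0.19 (camera adjusted p = 3.18e-06, and adjusted p = 0.409 with an estimated correlation). None of 20 elastic fibre genes passed over all genes by edgeR, where 0 rose and 0 fell, while 4 rose and 0 fell adjusted over the list alone. Fbn1, the fibrillin that forms microfibrils and the most abundant member, measured 6277 and 6731 CPM, and Eln, elastin, named after its values were seen, 1794 and 2352 CPM. The list's median was 0.21 (camera adjusted p = 3.34e-05, and adjusted p = 0.409 with an estimated correlation). Of 26 integrin and focal adhesion genes, Itgb5, whose product pairs with the alpha-v integrin, and Itga5, the fibronectin receptor subunit, rose, by 0.56 and 0.45 on the log2 scale. Among the others 0 fell and 24 did not pass, and adjusted over the list alone 5 rose and 0 fell (camera adjusted p = 3.34e-05, and adjusted p = 0.409 with an estimated correlation). Dcn and Itga5 lost their calls without any one library other than control 4 and Fra-2 2 (adjusted p up to 0.148 and 0.152), and Itgb5 without control 1, 2, 3, Fra-2 1 or Fra-2 3 (up to 0.0894). Fibroblast marker lists counted under other cell types also passed, with medians of 0.47 for adventitial fibroblast markers and 0.523 for matrix and lipid-type alveolar fibroblast markers (adjusted p = 0.409 with an estimated correlation for both). They share Dcn, Lum and Col14a1 with the fibrillar collagen list, Mfap5 with the elastic fibre list and Itga8 with the integrin list.

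Basement membrane genes moved in both directions in the libraries labelled Fra-2 transgenic. Col18a1, the source of endostatin, rose from 14.9 ± 2.72 to 32.2 ± 2.92 CPM (edgeR adjusted p = 0.00172). Hspg2, which encodes perlecan, rose from 522 ± 32.3 to 728 ± 42.1 CPM (edgeR adjusted p = 0.0215), and the X-linked collagen gene Col4a6 fell from 16.7 ± 0.866 to 8.08 ± 2.95 CPM (edgeR adjusted p = 0.0489). Of 20 members, 2 rose, 1 fell and 17 did not pass. Adjusted over the list alone, 5 rose and 2 fell (camera adjusted p = 0.00191, and adjusted p = 0.409 with an estimated correlation). Hspg2 lost its call without control 2, control 3, Fra-2 1, Fra-2 3 or Fra-2 4 (adjusted p up to 0.0949), and Col4a6 without any one library other than Fra-2 1 and Fra-2 2 (up to 0.152). Of 25 matrix proteases and inhibitors, Mmp19 alone rose and 0 fell, with 3 and 0 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0735, but 0.017 without control 4).

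Signalling lists that passed did so with members that mostly did not pass alone. For 27 PDGF, FGF and MAPK feedback genes, 0 rose and 0 fell in edgeR, both over all genes and adjusted over the list alone (camera adjusted p = 0.00469, and adjusted p = 0.409 with an estimated correlation). The list's camera adjusted p was 0.0679 without control 1. Pdgfra, the receptor that marks alveolar myofibroblast precursors, measured 1139 ± 156 and 1243 ± 128 CPM. Aldh1a2 was the 1 riser among 22 lipofibroblast and retinoid genes, 0 fell, and 3 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.00469, and adjusted p = 0.409 with an estimated correlation). The 17 chemokines and cytokines had 0 past the threshold over all genes and 3 risers adjusted over the list alone, Cxcl12, Cxcl13 and Il33 (camera adjusted p = 0.017, and adjusted p = 0.535 with an estimated correlation), which became 0.197 without control 1. The 14 Notch pathway genes had 0 past the threshold on either count (camera adjusted p = 0.0437, and adjusted p = 0.476 with an estimated correlation). The receptor gene Notch2 measured 209 and 219 CPM. The call of the list was kept only without control 3 or Fra-2 1 and lost without each of the other 6 libraries, with an adjusted p of up to 0.21.

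The contractile and AP-1 programmes of these cells did not pass. Of 25 smooth muscle contractile genes, 0 rose and 0 fell in edgeR, over all genes and adjusted over the list alone (camera adjusted p = 0.069). Acta2, which encodes smooth muscle actin, measured 3285 and 3411 CPM in control and labelled transgenic libraries, and Myh11, smooth muscle myosin, 4029 and 4385 CPM. Of 16 AP-1 family genes apart from Fosl2, 0 passed on either count (camera adjusted p = 0.237), with Jun at 362 and 433 CPM and Fosb at 499 ± 222 and 644 ± 200 CPM. Both lists passed upwards when some libraries were left out. The adjusted p of smooth muscle contractile genes was 0.00712 without control 4 and 0.00631 without Fra-2 2, and that of AP-1 family apart from Fosl2 was 0.0313 without control 3. Among 18 alveolar myofibroblast markers, the cardiac actin gene Actc1 rose from 99.2 ± 14.3 to 176 ± 38.6 CPM. Stc1, a secreted glycoprotein gene, rose from 470 ± 43.3 to 693 ± 101 CPM. Enpp2, which encodes the lysophosphatidic acid-producing enzyme autotaxin, fell from 571 ± 37.9 to 376 ± 74.9 CPM. The other 15 did not pass. Adjusted over the list alone 4 rose and 2 fell, and the list did not pass (camera adjusted p = 0.283). Actc1 lost its call without control 2, Fra-2 1, Fra-2 3 or Fra-2 4 (adjusted p up to 0.0934), Stc1 without control 1, 2, 3, Fra-2 1 or Fra-2 3 (up to 0.126), and Enpp2 without every library but Fra-2 2 (up to 0.185).

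None of the 25 mitosis genes or the 26 DNA replication genes passed in edgeR on either count, and neither list passed (camera adjusted p = 0.977 and 0.373). The proliferation marker Mki67 measured 398 and 346 CPM in control and labelled transgenic libraries, and Lig1, a ligase of replicating DNA, 97.8 and 95.4 CPM. Without Fra-2 2 both lists passed upwards (camera adjusted p = 0.0138 and 0.0314). Lists of TGF-beta, BMP and Hedgehog pathway genes, of immediate early and heat shock genes, of YAP and SRF targets, of sterol synthesis, of hypoxia and glycolysis, of class I antigen presentation and of the unfolded protein response also had 0 members past the threshold over all genes, and none passed (camera adjusted p from 0.0669 for the TGF-beta list to 0.866). Adjusted over the list alone, 2 TGF-beta, 2 BMP and 2 YAP and SRF target genes rose and 0 fell, with 0 in either direction for the other lists. The most abundant members were, in control and labelled transgenic libraries in turn, Ltbp2, of the latent TGF-beta binding protein family (3681 and 4244 CPM), Bmpr2, a BMP receptor (694 and 714 CPM), and Ptch1, the Hedgehog receptor (1115 and 1009 CPM). Those of the other lists included the early transcription factor Egr1 (3822 and 4211 CPM), the actin gene Actb (1722 and 1765 CPM), the sterol regulator Srebf2 (95.8 and 97.2 CPM) and the oxygen sensor Egln1 (175 and 169 CPM). The class I light chain B2m measured 197 and 238 CPM and the chaperone Hsp90b1 2364 and 2311 CPM. Single libraries decided some of these lists. TGF-beta pathway genes passed upwards without control 3, control 4 or Fra-2 3 (smallest camera adjusted p = 0.0276), immediate early and heat shock genes without control 3 (0.00839), and hypoxia and glycolysis genes without control 4 or Fra-2 2 (smallest 0.00878). The sterol synthesis genes passed downwards without control 1, Fra-2 1 or Fra-2 4 (smallest 0.00783). Among 16 oxidant defence genes, Srxn1, which restores oxidised peroxiredoxins, rose from 6.39 ± 0.539 to 15.5 ± 4.31 CPM (edgeR adjusted p = 0.00745) in the libraries labelled Fra-2 transgenic. Over all genes it was the 1 riser and 0 fell, adjusted over the list alone 4 rose and 1 fell, and the list of oxidant defence genes did not pass (camera adjusted p = 0.237, but 0.0166 without Fra-2 2). Xaf1 was the 1 riser, and 0 fell, among 18 interferon response genes on either count (camera adjusted p = 0.0735).

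**Figure D3:**
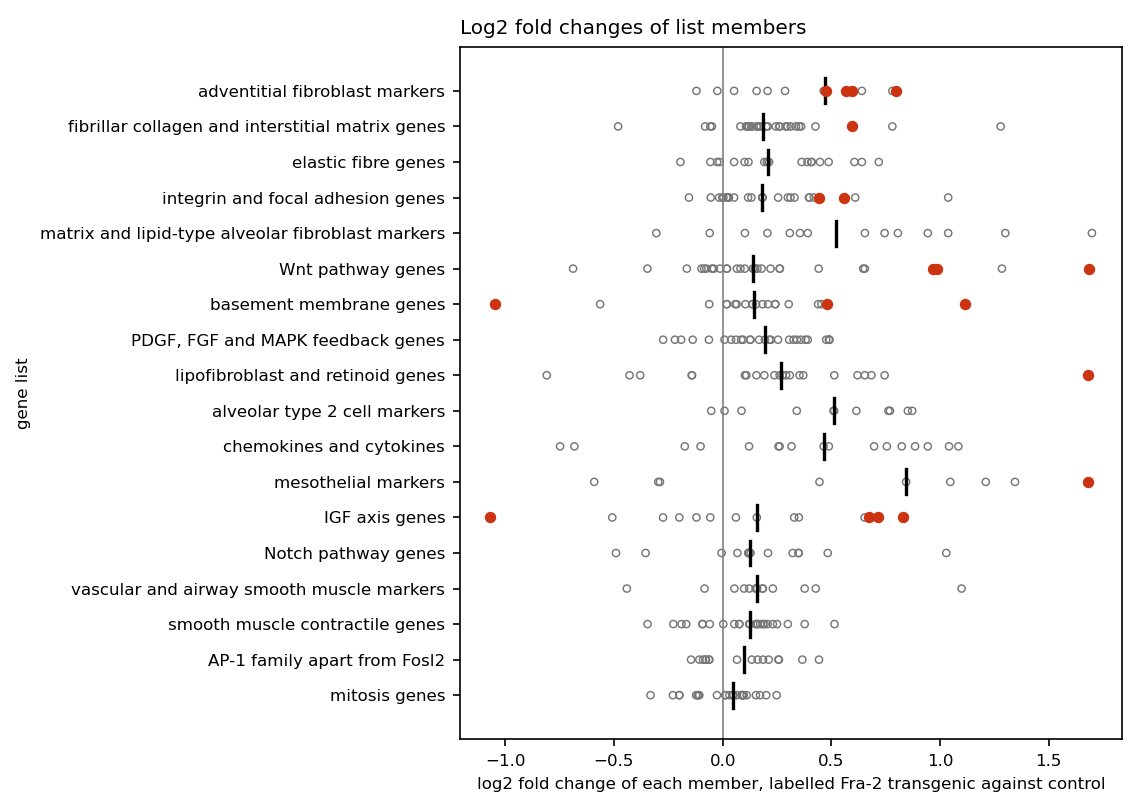
Log2 fold change of the libraries labelled Fra-2 transgenic against control (horizontal axis) for the members of the 15 gene lists past the threshold in camera and of 3 lists that did not pass, smooth muscle contractile, AP-1 family and mitosis genes (vertical axis). Open points are members that did not pass over all genes, filled points are members that did, and the bar is the list's median, which is highest for the mesothelial markers (0.85) and 0.05 for the mitosis genes.

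Markers of other lung cell types were counted in the same way, since a myofibroblast preparation can hold other cells. Adventitial fibroblast markers were higher in the libraries labelled Fra-2 transgenic: of 14, 4 rose, 0 fell and 10 did not pass, and 7 rose and 0 fell adjusted over the list alone. The median log2 fold change was 0.47 (camera adjusted p = 1.51e-06, and adjusted p = 0.409 with an estimated correlation). The risers were Dcn and, named after their values were seen, the matrix genes Dpt (361 ± 54.5 to 536 ± 69.7 CPM), Serpinf1 (78.7 ± 20.4 to 137 ± 20.2 CPM) and Pcolce2 (70.7 ± 7.33 to 98.3 ± 6.32 CPM). Each of these 3 lost its call in 6 of the 8 fits without 1 library: Dpt (adjusted p up to 0.172) and Pcolce2 (up to 0.2) kept it without control 4 or Fra-2 2, and Serpinf1 (up to 0.17) without control 1 or control 4. Col14a1, the most abundant adventitial marker, measured 647 ± 56.8 and 721 ± 9.39 CPM. The 14 matrix and lipid-type alveolar fibroblast markers had 0 past the threshold over all genes and 4 risers adjusted over the list alone, among them Itga8, an integrin of alveolar fibroblasts, named after its values were seen, at 80.2 and 165 CPM (camera adjusted p = 6.59e-05, and adjusted p = 0.409 with an estimated correlation). Macf1, a cytoskeletal linker gene and the most abundant of these markers, measured 1146 and 1100 CPM.

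Alveolar type 2 cell markers, 0 of 11 past the threshold on either count, had a camera adjusted p of 0.00631 (adjusted p = 0.594 with an estimated correlation), which became 0.161 without control 1 and 0.0771 without Fra-2 4. The list's median was 0.514, with 1.26 in the male and -0.0867 in the female libraries taken alone, fits of 2 against 2 libraries, and a difference between the sexes was not tested for this list. Etv5, a transcription factor of type 2 cells and the most abundant member, measured 68.0 and 68.4 CPM. Aldh1a2 was the 1 riser, and 0 fell, among 9 mesothelial markers on either count (camera adjusted p = 0.0272, and adjusted p = 0.476 with an estimated correlation). The list's adjusted p became 0.0504 without Fra-2 1 and 0.153 without Fra-2 4. The 13 vascular and airway smooth muscle markers had 0 past the threshold over all genes, 2 risers and 1 faller adjusted over the list alone, and a camera adjusted p of 0.0496 (adjusted p = 0.575 with an estimated correlation). It became 0.203 without control 1, 0.0848 without control 2, 0.101 without Fra-2 3 and 0.197 without Fra-2 4. These markers share Myh11, Cnn1, Lmod1, Actg2, Des, Acta2 and Mylk with the smooth muscle contractile list, which did not pass (camera adjusted p = 0.069). The remaining 14 lists of other cells and of RNA quality did not pass and had 0 members past the threshold over all genes. When single libraries were left out, endothelial markers passed upwards without control 2 or control 4 (smallest camera adjusted p = 0.0218) and erythroid markers downwards without control 1 (3.51e-05). The skeletal and cardiac muscle markers passed downwards without control 1, control 2, Fra-2 2 or Fra-2 3 (smallest 0.00145), and mitochondrially encoded genes without control 1 (0.0474). The haemoglobin gene Hbb-bs measured 29.8 ± 18.5 and 16.04 ± 10.01 CPM, the macrophage gene Lyz2 42.7 ± 17.5 and 51.7 ± 9.54 CPM, and the endothelial gene Eng 247 ± 28.9 and 303 ± 37.6 CPM. Of the epithelial lists, the most abundant members were Tppp3 of ciliated cells (35.1 and 26.8 CPM), the tight junction gene Cldn18 (22.9 and 25.8 CPM) and the caveolin gene Cav1 (350 and 306 CPM). The immune lists had the mast cell receptor Kit (6.22 and 8.66 CPM) and the T cell co-receptor Cd4 (3.63 and 2.42 CPM). Others were the cardiac myosin Myh6 (21.3 and 15.0 CPM), the matricellular gene Postn (1656 and 1798 CPM), the Schwann cell gene S100b (11.4 and 12.3 CPM) and the respiratory gene mt-Cytb (11572 and 11026 CPM). For airway epithelial markers the median and mean were above 0 while camera pointed down, and for chondrocyte markers the mean was above 0 while the median and camera were below. Adjusted over the list alone, 2 chondrocyte markers rose and 1 fell, 1 pericyte marker rose and 1 fell, 1 alveolar type 1 marker fell, and 0 passed in the other 11 of these lists. In all, 10 of 27 biology lists and 5 of 19 other lists passed in camera with its preset correlation, and without Fra-2 4 the other lists were 2. Of the 46, 0 passed with an estimated correlation (smallest adjusted p = 0.409) or in the directional test of fry (smallest adjusted p = 0.187). In the mixed test of fry, where members may move in both directions, 23 passed. That test does not compare a list with other genes, and it was not run on the splits. There were 35 splits of the 8 libraries into 4 and 4, the real one included. In camera with its preset correlation, 8 of them gave at least 10 biology lists and 15 gave at least 5 other lists.

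Libraries also differed in ways that followed the groups only in part. The share of counts outside protein-coding and mitochondrial ribosomal RNA genes was 1.06%, 1.56%, 0.989% and 0.738% in control 1 to control 4 and 0.866%, 1.05%, 0.857% and 0.676% in Fra-2 1 to Fra-2 4. It was highest in control 1, control 2, control 3 and Fra-2 2, so it is partly confounded with the group. Mitochondrial ribosomal RNA took 7.5% of the counts of control 2 against 0.578% to 2.26% in the other 7 libraries. With that noncoding share as a covariate, 56 genes were higher and 34 lower in the libraries labelled Fra-2 transgenic, and 86 of the 157 calls were kept. The adventitial list kept its call, with a median of 0.39. Without control 1 and control 2 together, 28 genes were higher and 15 lower, 42 of the calls were kept, and 2 biology lists passed in place of 10. List calls were lost with the noncoding share for Wnt, IGF and Notch genes and for alveolar type 2, mesothelial and smooth muscle markers, and with sex as a covariate for IGF and Notch genes and smooth muscle markers. Without control 1 and control 2, the fibrillar collagen, adventitial and matrix and lipid-type lists kept their calls and the other 12 lost them. The medians of these 3 lists were smaller in that fit, at 0.137 against 0.188, 0.303 against 0.47 and 0.221 against 0.523 in turn. The IGF median turned from 0.157 to -0.0526.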

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

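In this part, the tests of reads on Fosl2, of gene crowding on chromosome 11 and of Pi16, and the fits with the noncoding share or without control 1 and control 2, were chosen after the results they bear on, or the data, were seen. The splits of the libraries, the exchanges of labels and the fits without 1 library were chosen before.

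Single libraries stood apart from the other 3 of their group in 9 of 158 groups of values tested, where chance gives about 1 in 20 (7.9). Otof was 54.2 CPM in control 1 (32.2 to 34 in the other controls), Atp1b1 37.8 in control 1 (48.1 to 50.1) and Coro6 2.55 in control 1 (1.85 to 1.87). Igfbp5 was 1680 CPM in control 4 (1550 to 1570 in the others) and Sprn 1.43 in control 2 (3.19 to 3.55). Among the libraries labelled Fra-2 transgenic, Fra-2 3 held 23.6 CPM of Sfrp2 (15 to 16.4 in the others) and 1430 of Pdgfra (1160 to 1200), and Fra-2 2 held 48.1 of Csf1 (41.4 to 41.7) and 397 of Rpl4 (311 to 322). The calls of Otof, Atp1b1, Coro6, Igfbp5 and Sprn stayed past the threshold without each library in turn, while that of Sfrp2 was lost without Fra-2 3 (edgeR adjusted p = 0.0695).

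Of the 35 splits of the 8 libraries into 4 and 4, only the real one reached 111 higher or 46 lower genes. The larger direction of any other split held at most 9. A rank of 1 in 35 is the smallest share that these splits allow, so it argues against a chance split but cannot exclude one. For gene lists other splits reached the real counts: 8 of the 35 splits gave at least the real 10 biology lists (highest other 18), and 15 gave at least the real 5 other lists (highest other 9). The split that parts the 4 libraries with the highest noncoding shares (control 1, 2, 3 and Fra-2 2, 0.989% or more) from the rest gave 14 biology and 5 other lists but only 8 called genes. With that share as a covariate the real comparison gave 8 and 3 lists.

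Fosl2 was not higher in the libraries labelled Fra-2 transgenic although 157 genes differed. Too few reads on Fosl2 is argued against by the 95% interval of its log2 fold change, which ended at 0.427, below a doubling. A swap of one control and one transgenic label is argued against by the 16 such exchanges, which called at most 8 genes. One transgenic library without the transgene was tested by leaving out each in turn: the smallest unadjusted p was 0.0882, without Fra-2 4, where the interval ended at 0.513 and so still left out a doubling in the other 3. What may remain are a transgene transcript that is not counted on Fosl2 or is low in these cells at this age, neither of which was tested, so the called differences are those of the labels and not of a measured rise in Fosl2.

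Called genes crowded on chromosome 11 between 66211725 and 90390895 (GRCm38), where 15 of 376 tested genes (3.99%) were called against 0.951% elsewhere, Xaf1, Tmem100, Coro6, Pirt and Serpinf1 among them, while Fosl2 lies on chromosome 5. Gene density is argued against by random draws of as many tested genes, of which a share of 5e-04 had a window of 25 Mb as crowded anywhere in the genome, while the share was 0.0165 for 50 Mb but 0.141 for 10 Mb, so the crowding depends on the width. Regulation of the whole segment in one direction is argued against by its 9 higher and 6 lower genes. Their directions did not differ clearly from those elsewhere (Fisher's exact p = 0.376, two-sided). With 15 genes this test cannot tell whether some neighbours were regulated together. A segment of another strain carried beside the transgene could give such a block. The odds ratio of 4.33 comes from a window picked as the most crowded, so it does not test this. Such a segment cannot be told apart from regulation by Fra-2 without sequence variants, which counts do not hold.

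Adventitial and matrix fibroblast genes were higher in the libraries labelled Fra-2 transgenic, with an adventitial median log2 fold change of 0.47. Library quality is argued against as the whole cause by the fit with the noncoding share, where the median was 0.391 and the list still passed in camera (0.303, also passing, without control 1 and control 2). Unequal sexes are argued against by the design, since each group held 2 female and 2 male libraries. For the matrix and lipid-type list (median 0.523), library quality cannot be told apart from a difference of the groups. The median was 0.399 with the noncoding share and 0.221 without control 1 and control 2, a fit with fewer samples, and the list passed in both. A larger share of adventitial fibroblasts in the preparation may contribute and cannot be told apart from a change within the myofibroblasts: Pi16, the most specific marker, had a log2 fold change of 0.29 with an interval of -0.0621 to 0.637, which holds both 0 and the median. Dcn, Lum and Gsn are also expressed by other lung fibroblasts. The calls of both lists are lost with an estimated correlation (adjusted p = 0.409), and the split counts above apply to them.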

How the results depend on the processing

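The fits with sex, the noncoding share, 1 sex alone, mitochondrial ribosomal RNA left out and without control 1 and 2 were chosen after the data were seen. The others were planned. Counts are of genes higher and lower in the libraries labelled Fra-2 transgenic (111 and 46). Scaling, filtering, a non-robust fit, limma-voom and the sex covariate kept both within 1.5 times. They moved to 269 and 104 with DESeq2, 233 and 86 with voom sample weights, and 47 and 24 with a 2-fold minimum. In males alone they were 3 and 0, with 409 of 15837 tested genes at an unadjusted edgeR p under 0.05, a smaller share than chance gives. That fit of 2 against 2 libraries cannot show that the groups do not differ in males. Without control 1 and 2, which leaves fewer samples, the counts were 28 and 15. The higher count moved to 56 with the noncoding share and the lower to 73 at an adjusted p of 0.10. Without 1 library they ran from 50 to 153 and from 22 to 52. The causes of the moves with DESeq2, weights and the noncoding share were not tested. The Fosl2 log2 fold change ran from 0.01 to 0.24 without 1 library and passed in no fit.

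Whether replicate numbers pair the libraries is not settled. Same-numbered deviations correlated at 0.0018, 0.22, 0.08 and 0.31 for numbers 1 to 4. The highest correlation of each control with another number was 0.2, 0.16, 0.045 and 0.14 in turn. Control 2, 3 and 4 and Fra-2 2 and 4 correlated best with their own number, while control 1, Fra-2 1 and Fra-2 3 correlated best with another. With a replicate block, 137 genes were higher and 53 lower, and 10 biology and 8 other lists passed.

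Biology and other lists past the threshold (10 and 5) fell to 0 and 0 both with an estimated correlation and in the directional test of fry. Other lists were 3 with the noncoding share, and biology lists 2 without control 1 and 2. Without 1 library they ran from 7 to 14 and from 2 to 6. Without Fra-2 2 the DNA replication genes, not past the threshold otherwise and pointing down, pointed up and passed (camera adjusted p = 0.0314). Their signed -log10 p ran from -1.719 to 1.865 without 1 library. The cause was not tested. Over all settings, calls of named genes were kept 800 times and lost 175 times, and calls of lists were kept 213 times and lost 72 times. None of these reversed. For genes this largely follows from their selection, since in 156 of the 157 the groups do not overlap. Beside the DNA replication genes without Fra-2 2, 36 list results and 2 named-gene results that had not passed did so in a setting, the latter both Col2a1, with DESeq2 and voom sample weights. Fosl2 held at least 3914 reads per library, so depth is not what limits it. What depth limits for genes near the filter was not tested.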

Other observations

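The results in this part, on 3 ion channel genes, guidance genes and genes with few counts, were chosen after the called genes were seen, and the genes named here lie outside the rule for named genes.

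Axon guidance genes, which also steer mesenchymal and endothelial cells, were among the genes higher in the libraries labelled Fra-2 transgenic. Nrp2, a receptor for class 3 semaphorins and VEGF-C, rose from 46.4 ± 2.22 to 109 ± 27.7 CPM (edgeR adjusted p = 0.0012). The Robo ligand Slit2 rose from 110 ± 21.6 to 193 ± 28.1 CPM (edgeR adjusted p = 0.0138) and its relative Slit3 from 57.4 ± 10.4 to 95.6 ± 13.96 CPM (edgeR adjusted p = 0.0226). Slit2 lost its call without control 2, Fra-2 1 or Fra-2 3 (adjusted p up to 0.0676) and Slit3 without control 2, Fra-2 1 or Fra-2 3 (up to 0.106). Of 68 tested genes with guidance family symbols, 3 (4.41%) were called higher and 0 lower, against 0.703% of other genes called higher (one-sided Fisher's exact p = 0.013, the same after adjustment over the 2 families tested). That guidance genes are over-represented may hold as a hypothesis only, since the family was picked from the called genes and rests on 3 of them.

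Among the genes lower in the libraries labelled Fra-2 transgenic, the calcium channel gene Cacna1e fell from 22.4 ± 2.69 to 10.4 ± 2.92 CPM (edgeR adjusted p = 0.0102). The potassium channel gene Kcnn3 fell from 41.3 ± 3.91 to 25.2 ± 4.24 CPM (edgeR adjusted p = 0.0238) and Kcnq3 from 2.07 ± 0.74 to 0.186 ± 0.161 CPM (edgeR adjusted p = 0.0257). Cacna1e lost its call without control 2 (0.0508) or Fra-2 1 (0.0548), Kcnn3 without control 2, control 3, Fra-2 1 or Fra-2 3 (adjusted p up to 0.115) and Kcnq3 without control 1, 2, 3 or Fra-2 4 (up to 0.107). These 3 genes were picked from the called genes, and their falls may be followed up on other samples.

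Some called genes had at most 5 counts in every library of 1 group. Adgra1, an adhesion G protein-coupled receptor gene, held 1, 0, 0 and 0 counts in control 1 to control 4 and 78, 26, 35 and 136 in Fra-2 1 to Fra-2 4. The processed pseudogene Eif5al3-ps held 0, 4, 1 and 1 counts against 227, 173, 156 and 279, and its counts are uncertain because reads of a processed pseudogene can be shared with its parent gene. In the other direction, 1700016K19Rik held 14, 30, 17 and 30 counts in the controls against 1, 1, 3 and 4. Among the libraries read as male, Xist was 9 CPM in control 1 against 0.534, 0.902 and 0.385 in control 4, Fra-2 2 and Fra-2 4, and among those read as female, Ddx3y was 0.531 CPM in control 2 against 0.0938, 0.0288 and 0.0612 in control 3, Fra-2 1 and Fra-2 3. For scale, Xist was 457 to 883 CPM in the libraries read as female, and Ddx3y was 63 to 68.3 CPM in those read as male. Whether the values of control 1 and control 2 mark some mixing of the 2 was not tested. The fit without these 2 libraries, which leaves fewer samples, kept 42 of the 157 calls and lost 12 of the 15 list calls.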
